A study of Sus scrofa with 37 samples.

How the data were processed

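Total RNA of pig liver was sequenced in 37 libraries in 4 groups, which the treatment given for each sample defines. RNA was extracted with a lipid tissue kit and sequenced as paired-end reads on a NovaSeq instrument, per the labels' protocols. The deposited values are raw read counts per Ensembl gene, 1 table per sample. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned with HISAT2 to Sscrofa11.1 and counted with HTSeq, and the authors used DESeq2. Versions, the annotation release and the strand setting of the counting are not stated, so overlapping and antisense genes, and genes with near-identical copies, are uncertain. All values in the tables were whole numbers, and no further normalization had been applied to them.

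Each table held 31907 genes, of which 15029 could be paired with a symbol and 16878 could not. Genes with a symbol held 81.2% of the reads in genes, and 7586 genes were at 0 in every library. Reads in genes ran from 13.05 to 24.3 M per library. Reads outside genes made up 2.42 to 7.9%, ambiguous reads 10.91 to 19.01%, reads of low alignment quality 3.19 to 4.67%, unaligned reads 2.1 to 6.9% and reads with several alignments 5.55 to 9.74%. Mitochondrial mRNA took 2.66 to 26.31% of the reads in genes. Gene positions were taken from a RefSeq gene table of Sscrofa11.1, matched by symbol.

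Genes were filtered with filterByExpr over the 4 groups, which left 14025. Counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood, 1 mean per group, all 37 libraries). Tests were 2-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The 5 contrasts were infected against uninfected livers at each glucose supply, high against standard glucose in infected and in uninfected livers, and the interaction, as the infection fold change under high minus that under standard glucose. Levels are CPM with TMM factors. The groups, contrasts, filter, tests, gene lists and first set of alternatives were fixed before the data were examined.

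The 39 gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01, and again with a correlation estimated for each list and with fry. A list counted members as risen or fallen over all tested genes and, separately, adjusted over the list alone. Symbols missing from the tables shortened some lists, such as the acute phase list (13 of 24 symbols), the interferon gamma list (24 of 39), xenobiotic metabolism (19 of 39) and oxidative phosphorylation (55 of 73).

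Genes to be named were set by a rule. It took the 8 highest and 8 lowest fold changes of each contrast among passing genes with a symbol and a mean log2 CPM of at least 2, up to 4 members of each list with the smallest p, and a fixed panel. Y-linked genes were left out of the first part. From the genes of that rule, the ones in the text were picked after their values were seen. Some genes whose call or fold change depended on 1 library or setting were left out in doing so, so the named genes look steadier than the full set. Some other genes of the rule are not reported here. Infection fold changes of genes named for the interaction are given beside it.

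The fits were tested on simulated counts in which 200 genes per contrast changed by known amounts. At a log2 change of 1, the share recovered was 52.2% for infection under high glucose (13777 genes), 55.2% for infection under standard glucose (13814 genes), 68.7% for glucose in infected livers (13822 genes), 40.3% for glucose in uninfected livers (13815 genes) and 16.4% for the interaction (13821 genes). At a log2 change of 2 these shares were 90.9, 93.9, 92.4, 86.4 and 74.2%.

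Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, RLE factors, no filter, a filter of 1 CPM in 6 samples, removal of the 20 most abundant genes, 2 surrogate variables from sva 3.50.0, an erythroid score as covariate, fits of the compared groups alone, and each library left out in turn. Others were chosen after the data had been seen, namely replicates 5 and 6 of HIGH_CON summed, a sex term, the ambiguous share or the share of reads outside genes as covariate, and leaving out the 5 libraries with a mitochondrial mRNA share above 9%. Sex was called from a log2 CPM above 3 of the Y-linked gene EIF1AY. HIGH_CON replicates 1, 3, 5 and 6 lay above it, but in LOW_CON only replicates 1 and 3. HIGH_SE replicates 8 and 11 lay below it at 1.32 and 2.53 CPM, higher than the others called so, which leaves their call uncertain. Up to 100 other splits of the samples were fitted for each contrast, and for the interaction also 100 splits of the residuals of an additive model of log2 CPM, tested with limma's trended moderated t test. Shares of reads were compared by exact 2-sided permutation tests. No library was left out of the results, and the labels give no batch or litter to put into a model. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.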

Results

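Liver RNA of preterm pigs was sequenced in 37 libraries that cross infection with Staphylococcus epidermidis, a skin bacterium that causes sepsis in newborns, with the glucose supplied by parenteral (intravenous) nutrition. The label HIGH marks the high supply, and LOW marks the supply that the series' design text calls standard. The groups held 12 infected samples under high glucose (HIGH_SE), 13 infected samples under standard glucose (LOW_SE), 6 uninfected samples under high glucose (HIGH_CON) and 6 uninfected samples under standard glucose (LOW_CON). Depth ran from 13.05 to 24.3 M reads in genes per library, with a median of 17.01 M. By group it ran from 14.74 to 19.7 M in HIGH_SE, from 13.74 to 24.3 M in LOW_SE, from 15.21 to 20.84 M in HIGH_CON and from 13.05 to 18.7 M in LOW_CON. The test covered 14025 genes. Replicates are separate samples in the labels, which do not say whether each came from a different animal, nor give litter, sex or batch. Counts of replicates 5 and 6 of HIGH_CON were far closer to each other than those of any other pair of libraries from one group. The variance of their difference was 7.58 times its sampling variance, against 35.6 to 642 in the other 173 pairs. Levels are given in counts per M (CPM) as mean ± SD over the libraries of a group, and fold changes as log2 ± SE. The SE of a fold change is an approximation, its absolute log2 value divided by the square root of edgeR's F statistic. Positions are on Sscrofa11.1.

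Infection under high glucose (HIGH_SE vs HIGH_CON) raised chemokines, interferon-stimulated genes and acute phase proteins in the liver, together with the gluconeogenic enzyme gene PCK1. CXCL10, a chemokine that draws activated T cells (ENSSSCG00000032474, chromosome 8, 71693641 to 71695948), averaged 5910 ± 5200 CPM (n = 12) in infected and 15.5 ± 13.4 CPM (n = 6) in uninfected livers. Its log2 fold change was 8.58 ± 1.2, and all 12 infected libraries lay above the highest control. PCK1, which encodes the rate-limiting cytosolic enzyme of gluconeogenesis (ENSSSCG00000007507, chromosome 17, 57930507 to 57936523), averaged 1570 ± 1470 CPM (n = 12) against 44.2 ± 19.8 CPM (n = 6). That was a log2 fold change of 5.15 ± 0.53 (edgeR adjusted p = 4.09e-09), again with all 12 infected libraries above every control. ALB, the albumin gene, differed by -0.06 ± 0.48 (adjusted p = 0.937). The list of hepatocyte secreted proteins was not called, except with the ambiguous share in the model (median -0.48, camera adjusted p = 0.00499).

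Of the 36 measured members of the type I interferon list, 34 rose (34 adjusted over the list alone), with a median log2 fold change of 3.86 and a camera adjusted p of 2.75e-24, adjusted p = 0.0749 with an estimated correlation. UBE2L6, an interferon-induced conjugating enzyme, rose by 4.62 ± 0.49. In the interferon gamma and antigen presentation list 21 of 24 members rose (22 adjusted over the list alone, median 2.2, camera adjusted p = 4.13e-19, and 0.0175 with an estimated correlation). Examples were PSMB9, an immunoproteasome subunit, at 4.02 ± 0.32, the peptide transporter TAP1 at 4.26 ± 0.41 and the tryptophan-degrading enzyme IDO1 at 7.12 ± 0.68. IDO1 was near the detection limit in uninfected livers, at 0.135 ± 0.0819 CPM (n = 6).

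Cytokine and chemokine transcripts rose in 22 of 31 members (25 adjusted over the list alone, median 3.25, camera adjusted p = 2.12e-14, and 0.0143 with an estimated correlation). The monocyte chemokine CCL2 rose by 4.9 ± 0.56 and the neutrophil chemokine CXCL8 by 4.87 ± 0.61. IL6 rose by 4.98 ± 0.83, from 0.128 ± 0.115 CPM (n = 6) to 4.24 ± 4.44 CPM (n = 12). The TLR and NF-kB list had 27 of 38 members up and 1 down (28 and 1 adjusted over the list alone, median 1.66, camera adjusted p = 2.24e-15). The IL-6 and STAT3 list had 17 of 19 up (19 adjusted over the list alone, median 1.99, camera adjusted p = 8.05e-16), among them the feedback inhibitor SOCS3 at 4.05 ± 0.46. Both had an adjusted p of 0.0143 with an estimated correlation. Acute phase transcripts rose in 12 of 13 members (12 adjusted over the list alone, median 2.77, camera adjusted p = 1.19e-11, and 0.00887 with an estimated correlation). The fibrinogen genes FGB and FGG rose by 3 ± 0.38 and 3.05 ± 0.37, the lipopolysaccharide-binding protein gene LBP by 2.77 ± 0.37, and the antibody transporter gene PIGR by 3.52 ± 0.45. The gene of the iron hormone hepcidin, HAMP, rose by 3.18 ± 0.68. The iron list had 10 of 21 members up and 2 down (11 and 2 adjusted over the list alone, median 0.48, camera adjusted p = 0.00439, and 0.0328 with an estimated correlation).

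Among metabolic lists, gluconeogenesis and amino acid supply had 10 of 20 members up and none down (10 adjusted over the list alone, median 0.72, camera adjusted p = 8.47e-05, adjusted p = 0.0749 with an estimated correlation). G6PC1, which releases free glucose, rose by 3.12 ± 0.53 (3.93 without HIGH_CON replicate 3). In the insulin and FOXO list 10 of 20 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.85, camera adjusted p = 0.000812, and 0.0251 with an estimated correlation). The glucocorticoid list had 8 of 15 members up (9 adjusted over the list alone, median 0.72, camera adjusted p = 5.68e-05, and 0.0143 with an estimated correlation). Urea cycle and amino acid catabolism had 16 of 31 up and 5 down (16 and 5 adjusted over the list alone, median 0.7, camera adjusted p = 8.87e-05, adjusted p = 0.238 with an estimated correlation), with the arginase gene ARG1 at 2.18 ± 0.27. Glycolysis had 13 of 27 up and 2 down (20 and 2 adjusted over the list alone, median 0.91, camera adjusted p = 6.18e-05, adjusted p = 0.123 with an estimated correlation). Its members included the hexokinase gene HK2 at 3.9 ± 0.64 and the phosphofructokinase gene PFKP at 1.73 ± 0.33. Complement had 8 of 24 up and 2 down (10 and 3 adjusted over the list alone, median 0.43, camera adjusted p = 0.00611, adjusted p = 0.277 with an estimated correlation), with C3 at 2.5 ± 0.28 and C6 at 3.8 ± 0.49. Coagulation had 18 of 29 up and 2 down (18 and 2 adjusted over the list alone, median 0.98, camera adjusted p = 0.00016, adjusted p = 0.149 with an estimated correlation). The hypoxia list had 18 of 25 up (18 adjusted over the list alone, median 1.41, camera adjusted p = 7.61e-08, adjusted p = 0.176 with an estimated correlation). The unfolded protein list had 18 of 28 up and 1 down (18 and 2 adjusted over the list alone, median 0.7, camera adjusted p = 7.73e-06, adjusted p = 0.138 with an estimated correlation). Cell death and p53 targets had 11 of 22 up and 2 down (12 and 2 adjusted over the list alone, median 0.66, camera adjusted p = 0.000266, adjusted p = 0.0796 with an estimated correlation).

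T and NK cell markers rose in 8 of 17 members (8 adjusted over the list alone, median 0.88, camera adjusted p = 0.00755, adjusted p = 0.238 with an estimated correlation). Stellate cell and fibroblast markers fell in 4 of 20 and rose in 1 (4 and 1 adjusted over the list alone, median -0.3, camera adjusted p = 0.041, adjusted p = 0.414 with an estimated correlation). That call ended without HIGH_SE replicate 8, HIGH_CON replicate 3 or HIGH_CON replicate 4 (medians -0.25, -0.13 and -0.19, adjusted p from 0.0741 to 0.0816). It ended too with a sex term (0.0624), with the share of reads outside genes in the model (0.0916) and without the 5 libraries of high mitochondrial mRNA share (median -0.1, 0.132). The fatty acid oxidation list had 11 of 33 down and 3 up (11 and 3 adjusted over the list alone, median -0.16, camera adjusted p = 0.0467, adjusted p = 0.617 with an estimated correlation). It was not called in 10 of the 37 fits that left out 1 library, namely HIGH_SE replicates 1, 4, 5 and 6, HIGH_CON replicates 1, 3, 5 and 6, LOW_SE replicate 6 and LOW_CON replicate 4 (adjusted p from 0.0504 to 0.125). In these fits the median ran from -0.23 without HIGH_CON replicate 3 to -0.05 without HIGH_CON replicate 1. Nor was the fatty acid oxidation list called with the erythroid score (0.0657) or the ambiguous share (0.0636) in the model, with HIGH_CON replicates 5 and 6 summed (0.0709) or without those 5 libraries (0.0699). The Kupffer cell list was not called (camera adjusted p = 0.247), except with the share of reads outside genes in the model (0.0145), although CSF1R, the receptor that maintains macrophages, fell by 1.13 ± 0.18 on the log2 scale. CLEC4F, a Kupffer cell lectin outside that list, fell by 4.55 ± 0.68 on the log2 scale. Erythroid, endothelial, megakaryocyte and neutrophil markers were not called, with camera adjusted p of 0.379, 0.629, 0.201 and 0.0815. Fry did call the megakaryocyte markers (median 0.49, fry adjusted p = 0.0103). Neutrophil markers were called without HIGH_CON replicate 3, HIGH_CON replicate 4 or HIGH_SE replicate 11 (adjusted p from 0.0379 to 0.0468). In all, edgeR's quasi-likelihood test called 4513 genes, 2357 higher and 2156 lower, and camera called 20 of 39 lists, 8 of them with an estimated correlation. With limma voom and sample quality weights 7209 genes were called.

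**Figure D1:**
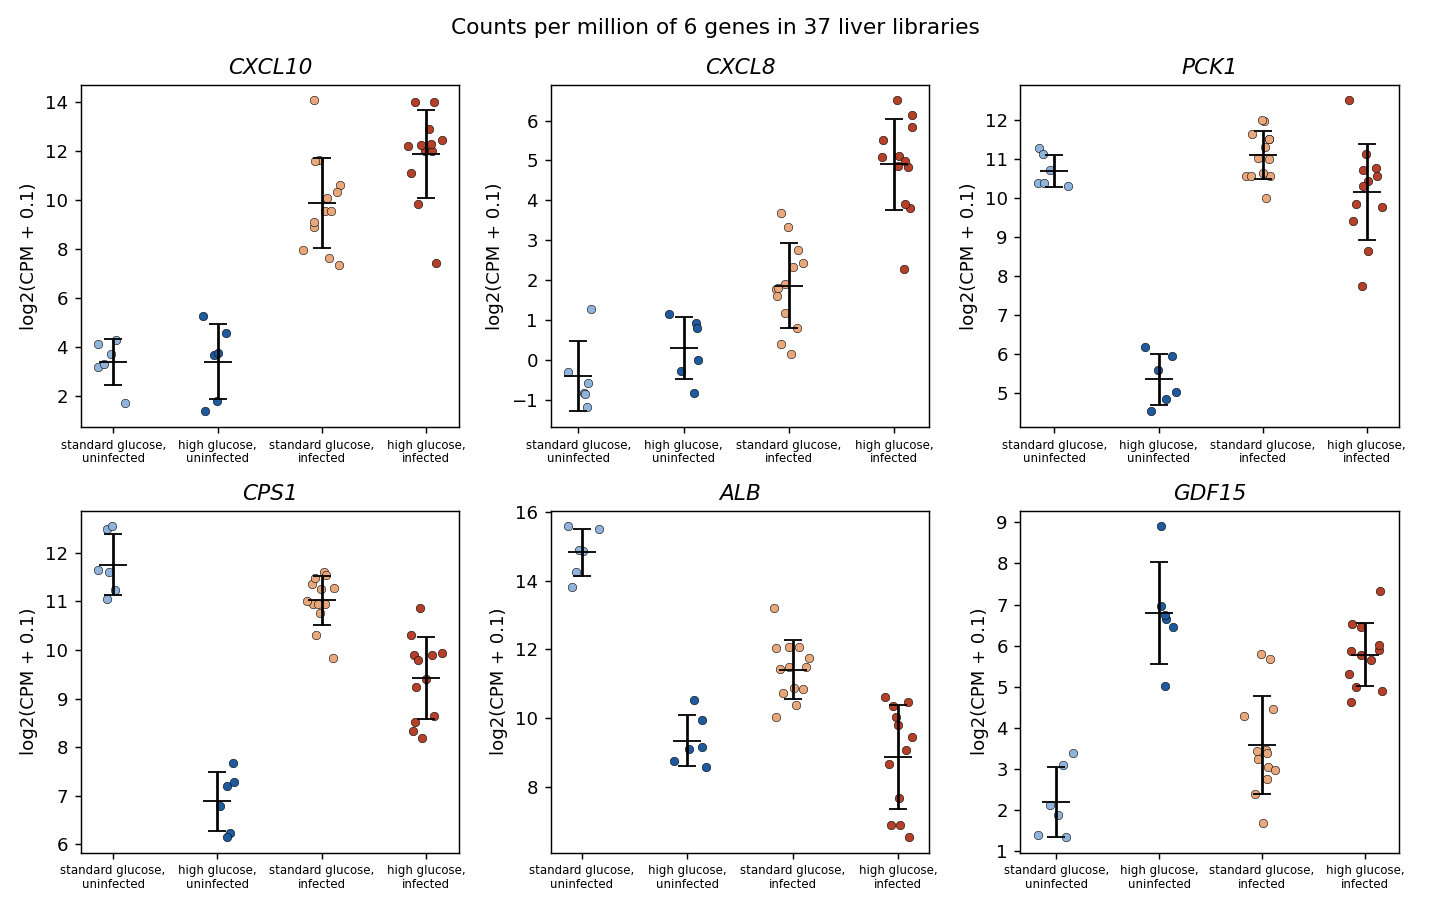
Counts per M of CXCL10, CXCL8, PCK1, CPS1, ALB and GDF15 in each of the 37 libraries, as log2 of CPM plus 0.1 on the y axis, by group on the x axis; points are libraries, and bars give the mean and SD. PCK1 averaged 44.2 CPM in uninfected livers under high glucose and 1570 to 2400 CPM in the other 3 groups.

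Infection under standard glucose (LOW_SE vs LOW_CON) raised chemokines and interferon-stimulated genes, and lowered albumin and many other hepatocyte products. CXCL9, an interferon-induced T cell chemokine (ENSSSCG00000032777, chromosome 8, 71665541 to 71670236), averaged 1020 ± 583 CPM (n = 13) in infected and 2.19 ± 1.89 CPM (n = 6) in uninfected livers. Its log2 fold change was 8.9 ± 0.81, and all 13 infected libraries lay above every control. ALB (ENSSSCG00000008948, chromosome 8, 69643427 to 69663152) fell from 31700 ± 14000 CPM (n = 6) to 3230 ± 2180 CPM (n = 13), a log2 fold change of -3.29 ± 0.46 (edgeR adjusted p = 1.72e-06), with all 13 infected libraries below every control. The hepatocyte secreted list had 19 of 23 members down and none up (21 adjusted over the list alone, median -1.21, camera adjusted p = 4.49e-09, adjusted p = 0.15 with an estimated correlation). The fetal albumin homologue AFP fell by 1.34 ± 0.24 on the log2 scale.

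The type I interferon list had 34 of 36 members up (34 adjusted over the list alone, median 3.88, camera adjusted p = 2.46e-25, adjusted p = 0.103 with an estimated correlation). UBE2L6 rose by 5.24 ± 0.51 and ISG15 by 7.12 ± 1.08 (6.17 without LOW_SE replicate 5). The interferon gamma list had 19 of 24 up (20 adjusted over the list alone, median 2.22, camera adjusted p = 1.42e-18, adjusted p = 0.0738 with an estimated correlation), with PSMB9 at 5.03 ± 0.34, TAP1 at 4.34 ± 0.41 and IDO1 at 6.76 ± 0.73. Cytokines and chemokines had 18 of 31 up and 1 down (20 and 1 adjusted over the list alone, median 1.79, camera adjusted p = 2.67e-05, adjusted p = 0.204 with an estimated correlation). CXCL8 rose by 2.43 ± 0.57 (3.11 without LOW_CON replicate 4), while IL6 differed by 1.86 ± 0.86 and did not pass (adjusted p = 0.0997). The TLR and NF-kB list had 23 of 38 up and 2 down (25 and 3 adjusted over the list alone, median 0.87, camera adjusted p = 2.28e-06, adjusted p = 0.15 with an estimated correlation). The IL-6 and STAT3 list had 16 of 19 up (17 adjusted over the list alone, median 1.25, camera adjusted p = 2e-11, adjusted p = 0.0738 with an estimated correlation), with SOCS3 at 2.4 ± 0.41 (3.11 without LOW_CON replicate 1). Acute phase transcripts rose in 10 of 13 members (10 adjusted over the list alone, median 1.3, camera adjusted p = 2.62e-06, adjusted p = 0.0738 with an estimated correlation). FGG rose by 1.54 ± 0.34 and the iron-binding lipocalin gene LCN2 by 2.85 ± 0.41. HAMP differed by 0.26 ± 0.57 (adjusted p = 0.762). The unfolded protein list had 16 of 28 up and 2 down (17 and 2 adjusted over the list alone, median 0.79, camera adjusted p = 3.03e-05, adjusted p = 0.204 with an estimated correlation), and cell death and p53 targets 12 of 22 up (15 up and 1 down adjusted over the list alone, median 0.77, camera adjusted p = 8.02e-05, adjusted p = 0.103 with an estimated correlation). The glucocorticoid list had 6 of 15 up and 2 down (6 and 2 adjusted over the list alone, median 0.99, camera adjusted p = 0.0291, adjusted p = 0.208 with an estimated correlation).

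Several metabolic lists, though not all, were lower in infected livers under standard glucose. Glycolysis had 10 of 27 members up and 3 down (11 and 3 adjusted over the list alone, median 0.55) and was not called (camera adjusted p = 0.0774). It was called as higher without LOW_SE replicate 1, LOW_SE replicate 3 or LOW_SE replicate 4 (0.0368 to 0.0484). The TCA cycle list had 3 of 30 up and 4 down (3 and 4 adjusted over the list alone, median 0.01, camera adjusted p = 0.993). Fatty acid oxidation had 18 of 33 members down (18 adjusted over the list alone, median -0.68, camera adjusted p = 5.25e-07, adjusted p = 0.144 with an estimated correlation), with the acyl-CoA dehydrogenase gene ACADL at -1.12 ± 0.21. Cholesterol synthesis had 14 of 23 down (14 adjusted over the list alone, median -0.71, camera adjusted p = 1.92e-05, adjusted p = 0.238 with an estimated correlation). Bile acid synthesis and transport had 10 of 20 down and 1 up (11 and 1 adjusted over the list alone, median -0.92, camera adjusted p = 7.13e-05, adjusted p = 0.15 with an estimated correlation). The bile acid uptake carrier gene SLC10A1 fell by 2.26 ± 0.31 on the log2 scale, and CYP7A1, the rate-limiting enzyme gene of bile acid synthesis, by 3.98 ± 0.7 from a low 2.92 ± 2.6 CPM (n = 6). Urea cycle and amino acid catabolism had 16 of 31 down and 2 up (18 and 2 adjusted over the list alone, median -0.63, camera adjusted p = 0.000223, adjusted p = 0.267 with an estimated correlation). OTC, of the urea cycle, fell by 3 ± 0.49 on the log2 scale. Gluconeogenesis and amino acid supply had 9 of 20 down (9 adjusted over the list alone, median -0.35, camera adjusted p = 0.0134, adjusted p = 0.267 with an estimated correlation). FBP1, a committed enzyme of gluconeogenesis, fell by 2.79 ± 0.38 and G6PC1 by 1.27 ± 0.42 on the log2 scale, while PCK1 differed by 0.47 ± 0.4 (adjusted p = 0.398). GYS2, the liver glycogen synthase gene, fell by 2.37 ± 0.41 on the log2 scale, whereas HK2 rose by 3.22 ± 0.63. Xenobiotic metabolism had 7 of 17 down (8 down and 1 up adjusted over the list alone, median -0.83, camera adjusted p = 0.00259, adjusted p = 0.229 with an estimated correlation). Oxidative phosphorylation had 14 of 53 down (19 down and 2 up adjusted over the list alone, median -0.44, camera adjusted p = 0.000479). The mitochondrially encoded genes had 5 of 13 down (5 adjusted over the list alone, median -0.61, camera adjusted p = 0.0149). Both had an adjusted p = 0.522 with an estimated correlation. The call for both ended without LOW_CON replicate 5 (medians -0.14 and -0.34, camera adjusted p = 0.0597 and 0.0681), whose mitochondrial genes stood above those of its group, as did that of the glucocorticoid list (0.0574). The glucocorticoid call also ended without the 5 libraries of high mitochondrial mRNA share (0.0733), and fry did not call the mitochondrially encoded genes (0.0581).

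Kupffer cell and macrophage markers fell in 10 of 19 members (10 down and 1 up adjusted over the list alone, median -0.54, camera adjusted p = 0.00052, adjusted p = 0.252 with an estimated correlation), with CSF1R at -1.31 ± 0.18. Stellate cell and fibroblast markers fell in 9 of 20 and rose in 1 (9 and 1 adjusted over the list alone, median -0.58, camera adjusted p = 1.78e-05, adjusted p = 0.103 with an estimated correlation). Neutrophil markers had 6 of 18 up and 1 down (6 and 1 adjusted over the list alone, median 1.08) and were not called (camera adjusted p = 0.0806). They were called without LOW_SE replicate 1, LOW_SE replicate 3 or LOW_CON replicate 6 (0.0386 to 0.0488). Endothelial markers had 2 of 17 up and 6 down (2 and 6 adjusted over the list alone, median -0.08, camera adjusted p = 0.0806) and were called as lower without LOW_CON replicate 4 (0.0367). Fry called the endothelial markers too (0.0186). The hypoxia list had 8 of 25 up (8 adjusted over the list alone, median 0.72, camera adjusted p = 0.0806) and was called without LOW_SE replicate 4 or LOW_SE replicate 8 (0.0483 and 0.0485). The cell cycle list had 4 of 29 up (none adjusted over the list alone, median 0.47, camera adjusted p = 0.0123, adjusted p = 0.522 with an estimated correlation), and erythroid markers had 5 of 24 up (1 adjusted over the list alone, camera adjusted p = 0.185). The cell cycle call ended with the erythroid score in the model (median 0.18, 0.196) and with fry (0.096). The edgeR test called 4098 genes, 2005 higher and 2093 lower. Camera called 21 lists, and none passed with an estimated correlation; the smallest of those adjusted p was 0.0738, and fry called 24 lists.

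Fold changes with infection were correlated between the glucose groups, which share no library. Across 14025 genes Pearson's r was 0.723 (jackknife SE over libraries 0.0427) and Spearman's rho 0.64; genes are not independent replicates. A rise was called in both groups for 1126 genes, against 337 for independent lists, and a fall in both for 991, against 322. Another 66 genes were called in opposite directions, 47 of them higher with infection under high and lower under standard glucose.

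**Figure D2:**
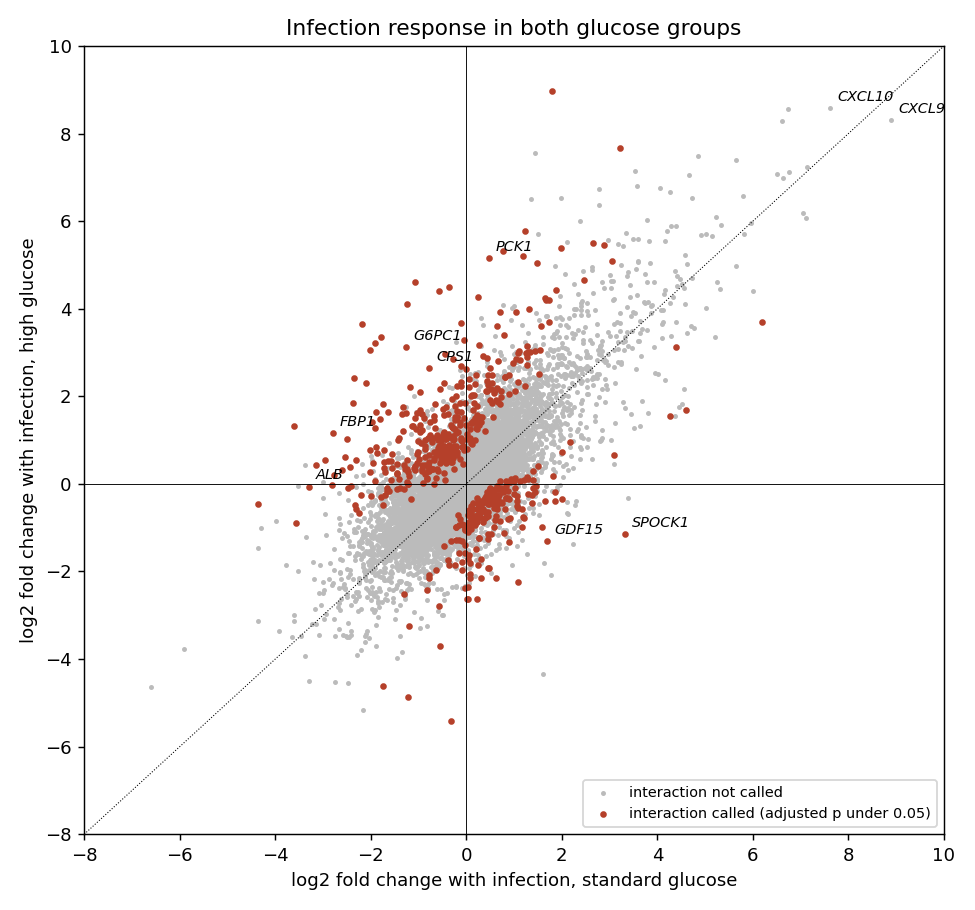
Log2 fold change with infection under standard glucose (x axis) and under high glucose (y axis) for each of 14025 genes; the dotted line marks equal changes, and the 570 genes in red differ between the glucose groups by edgeR's interaction test. PCK1, G6PC1, CPS1 and FBP1 lie above the line, and GDF15 and SPOCK1 below it.

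In uninfected livers (HIGH_CON vs LOW_CON), high glucose went with lower transcripts of glucose production, amino acid breakdown and secreted liver proteins. PCK1 averaged 44.2 ± 19.8 CPM (n = 6) under high and 1730 ± 522 CPM (n = 6) under standard glucose, a log2 fold change of -5.29 ± 0.56 (edgeR adjusted p = 8.84e-09). CPS1, which catalyses the first step of the urea cycle (ENSSSCG00000016159, chromosome 15, 113210038 to 113339086), averaged 127 ± 51.3 against 3750 ± 1680 CPM (n = 6 each), a change of -4.88 ± 0.43 (edgeR adjusted p = 3.64e-10). ALB averaged 736 ± 426 against 31700 ± 14000 CPM (n = 6 each), a change of -5.43 ± 0.68. GDF15, a stress-induced hormone gene (ENSSSCG00000034260, chromosome 2, 59409035 to 59411356), was higher by 4.9 ± 0.69 (4.12 without HIGH_CON replicate 4). For PCK1, CPS1, ALB and GDF15 all 6 libraries of one group lay outside the range of the other.

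Urea cycle and amino acid catabolism had 28 of 31 members lower and none higher (28 adjusted over the list alone, median -2.44, camera adjusted p = 7.87e-27, and 0.0017 with an estimated correlation). Mean log2 CPM of the list ran from 4.92 to 5.7 in HIGH_CON and from 7.61 to 8.64 in LOW_CON. The lysine-degrading enzyme gene AASS differed by -4.58 ± 0.4, CTH, which cleaves cystathionine, by -3.87 ± 0.4, and HPD, of tyrosine breakdown, by -7.96 ± 0.87 (-6.96 without LOW_CON replicate 5). Gluconeogenesis and amino acid supply had 17 of 20 lower (18 adjusted over the list alone, median -1.75, camera adjusted p = 3.55e-15, and 0.0012 with an estimated correlation). FBP1 differed by -6.21 ± 0.59, G6PC1 by -5.62 ± 0.63 (-6.42 without HIGH_CON replicate 3) and the pyruvate carboxylase gene PC by -3.39 ± 0.4. Glycogen metabolism had 7 of 20 lower and 1 higher (8 and 1 adjusted over the list alone, median -0.46, camera adjusted p = 0.0102), with GYS2 at -3.67 ± 0.56. Fatty acid oxidation had 22 of 33 lower and 1 higher (23 and 2 adjusted over the list alone, median -1.03, camera adjusted p = 4.24e-10), with the peroxisomal enzyme gene EHHADH at -3.5 ± 0.38. The TCA cycle and pyruvate dehydrogenase list had 16 of 30 lower (17 adjusted over the list alone, median -0.65, camera adjusted p = 7.94e-08), with SUCLA2 at -2.06 ± 0.28. Bile acid synthesis and transport had 13 of 20 lower (16 adjusted over the list alone, median -1.47, camera adjusted p = 5.7e-08). Xenobiotic metabolism had 10 of 17 lower (11 adjusted over the list alone, median -1.9, camera adjusted p = 1.56e-07), with the sulfotransferase gene SULT2A1 at -6.33 ± 0.68 (-7.22 without HIGH_CON replicate 3). Iron handling had 9 of 21 lower and 1 higher (9 and 1 adjusted over the list alone, median -0.69, camera adjusted p = 0.00603). Coagulation had 16 of 29 lower and 1 higher (17 and 1 adjusted over the list alone, median -1.13, camera adjusted p = 4e-08), with F9 at -2.24 ± 0.29 and FGB at -2.69 ± 0.4. These 7 lists from glycogen to coagulation each had an adjusted p of 0.0373 with an estimated correlation. Complement had 17 of 24 lower (17 adjusted over the list alone, median -1.12, camera adjusted p = 1.37e-09, and 0.0268 with an estimated correlation).

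Other lists were called with the preset correlation alone. The hepatocyte secreted list had 14 of 23 lower (15 adjusted over the list alone, median -1.12, camera adjusted p = 4e-08, adjusted p = 0.152 with an estimated correlation), with APOA2 at -4.22 ± 0.6. Acute phase transcripts were lower in 7 of 13 members (8 adjusted over the list alone, median -1.01, camera adjusted p = 0.000306, adjusted p = 0.0992 with an estimated correlation), with LBP at -2.99 ± 0.4. Oxidative phosphorylation had 28 of 53 lower and 1 higher (33 and 1 adjusted over the list alone, median -0.7, camera adjusted p = 2.13e-09) and glycolysis 9 of 27 lower and 1 higher (11 and 1 adjusted over the list alone, median -0.63, camera adjusted p = 0.00496); both had an adjusted p = 0.281 with an estimated correlation. Cholesterol synthesis had 11 of 23 lower and 1 higher (13 and 1 adjusted over the list alone, median -0.8, camera adjusted p = 0.00938, adjusted p = 0.5 with an estimated correlation). Lipogenesis and carbohydrate-responsive genes had 14 of 29 lower and 4 higher (14 and 5 adjusted over the list alone, median -0.45, camera adjusted p = 0.0113, adjusted p = 0.171 with an estimated correlation). The fatty acid synthase gene FASN differed by -0.45 ± 0.25 (adjusted p = 0.196) and the glucose-responsive gene TXNIP by 0.57 ± 0.36 (adjusted p = 0.254). The insulin and FOXO list had 8 of 20 lower and 2 higher (9 and 2 adjusted over the list alone, median -0.62, camera adjusted p = 0.0191, adjusted p = 0.115 with an estimated correlation). Of its members, PCK1 and G6PC1, which insulin represses, were lower, and IGFBP1, also repressed by insulin, differed by 0.09 ± 0.44 (adjusted p = 0.908). Kupffer cell markers were lower in 6 of 19 members (6 adjusted over the list alone, median -0.63, camera adjusted p = 0.000558, adjusted p = 0.257 with an estimated correlation). The interferon gamma list had 7 of 24 higher (8 adjusted over the list alone, median 0.57, camera adjusted p = 0.0191, adjusted p = 0.606 with an estimated correlation), with PSMB8 at 1.89 ± 0.3 and TAP2 at 1.93 ± 0.31. That call ended with fry (0.0719) and with the share of reads outside genes in the model (0.0847), and the latter ended the cholesterol call too (0.0614). The unfolded protein list was not called (5 of 28 higher and 8 lower, 5 and 15 adjusted over the list alone, camera adjusted p = 0.0824), but was called as lower without LOW_CON replicate 2 or LOW_CON replicate 6 (0.027 and 0.026). Its stress-induced members ATF3 and TRIB3 were higher, by 3.17 ± 0.5 and 1.9 ± 0.38. STC2, a secreted stress-induced glycoprotein gene, was higher by 4.37 ± 0.71 and BBC3, a p53 target that promotes apoptosis, by 3.66 ± 0.41. The cell death and p53 list had 6 of 22 higher and 2 lower (6 and 2 adjusted over the list alone, median 0.34) and was not called (camera adjusted p = 0.0737). It was called as higher without HIGH_CON replicate 3, HIGH_CON replicate 5 or HIGH_CON replicate 6 (0.0411 to 0.0496), with the share of reads outside genes in the model (0.0392) and with fry (0.00568).

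The edgeR test called 3852 genes, 1879 higher and 1973 lower under high glucose, and camera called 19 lists. The share of reads outside annotated genes was 6.51 ± 1.1% (n = 6) in HIGH_CON and 4.42 ± 1.14% (n = 6) in LOW_CON, by an exact two-sided permutation test p = 0.013 and adjusted p = 0.039 over 12 such comparisons. That test counted HIGH_CON replicates 5 and 6, at 6.69 and 7.61%, as separate samples, and was not repeated with them merged. With the share of reads outside genes as a covariate 1879 genes were called, 1711 of them among the 3852, and the urea cycle list kept a median of -1.97. Limma voom with sample quality weights called 6619.

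**Figure D3:**
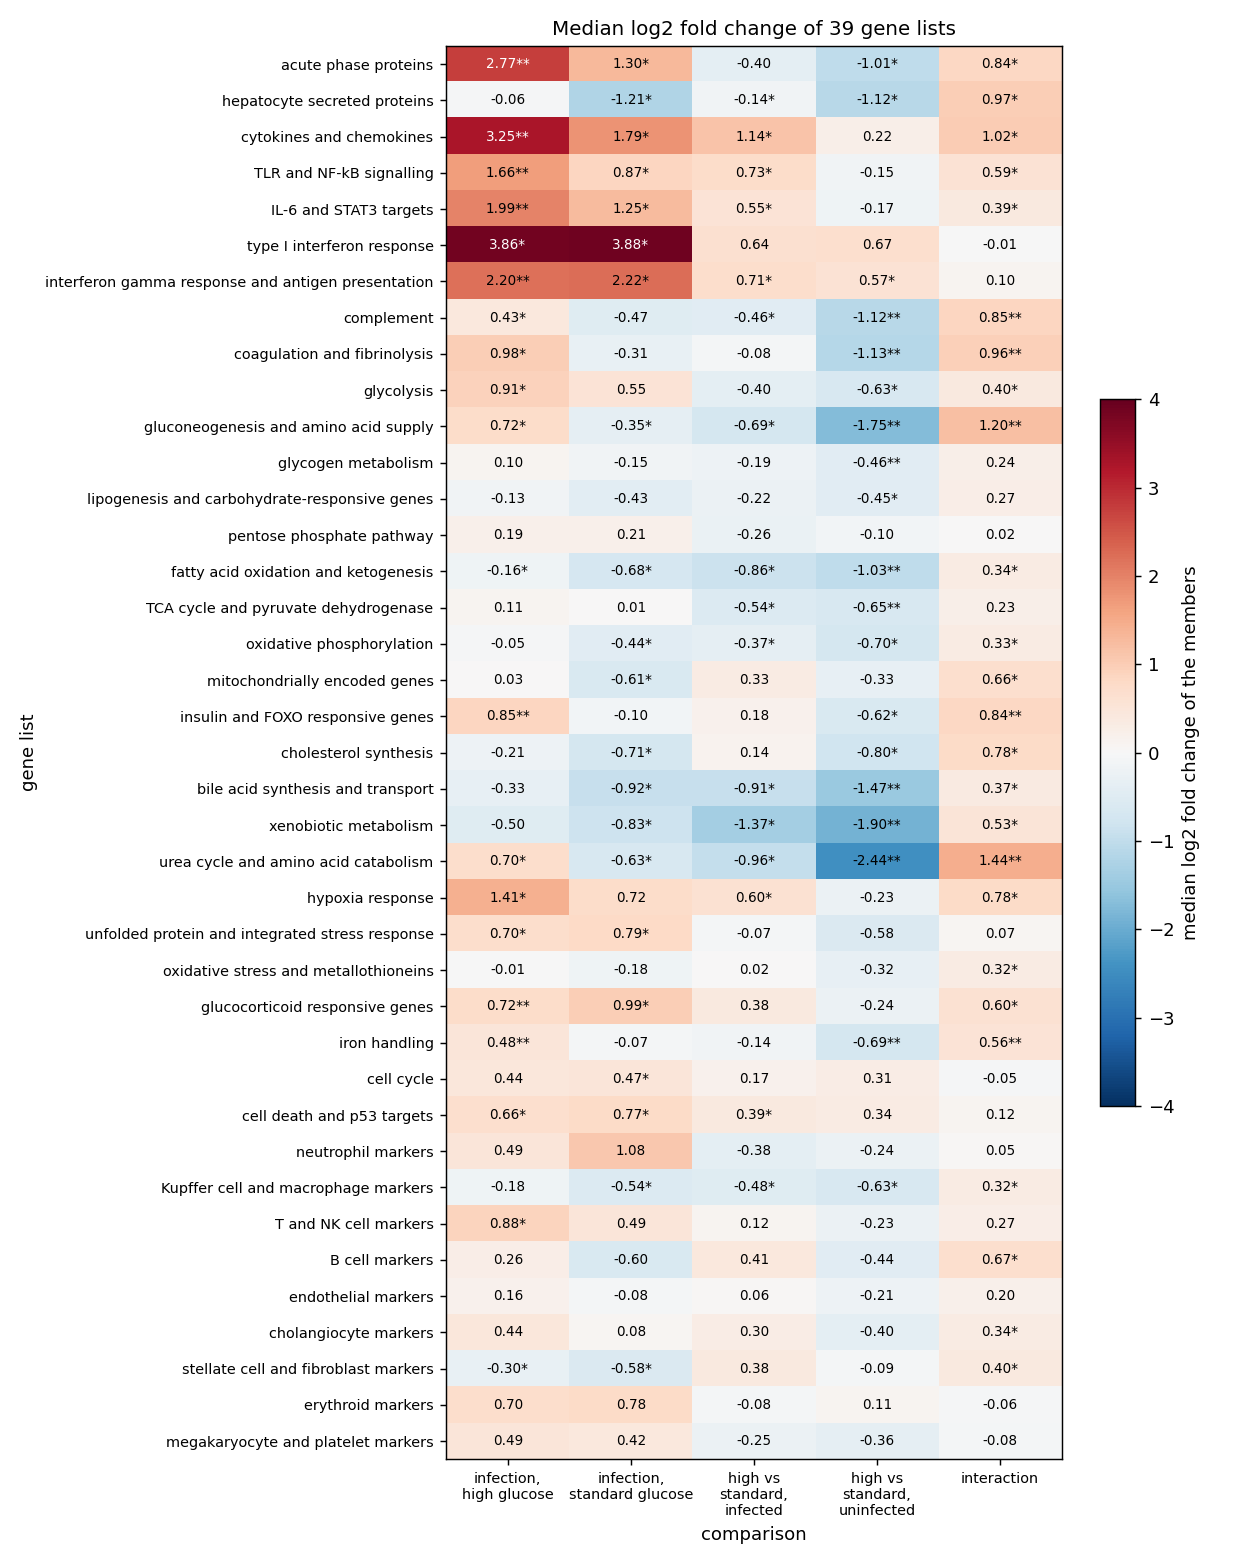
Median log2 fold change of the measured members of the 39 gene lists (y axis) in each of the 5 comparisons (x axis), with the value printed and coded by colour; 1 star marks a camera adjusted p under 0.05 with the preset correlation, and 2 stars that it holds with an estimated correlation too. The type I interferon list has the highest medians, 3.86 and 3.88, and the urea cycle list the lowest, -2.44.

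In infected livers (HIGH_SE vs LOW_SE), high glucose went with higher cytokine, chemokine and NF-kB transcripts, and with lower mitochondrial and amino acid enzymes. CXCL8 (ENSSSCG00000008953, chromosome 8, 69932646 to 69935861) averaged 37.8 ± 24.7 CPM (n = 12) under high and 4.52 ± 3.47 CPM (n = 13) under standard glucose, a log2 fold change of 3.07 ± 0.39 (edgeR adjusted p = 3.57e-07); 11 of 12 libraries lay above the highest of the other group. HPD (ENSSSCG00000009805, chromosome 14, 30845608 to 30857658) averaged 18 ± 16.1 against 686 ± 414 CPM, a change of -5.25 ± 0.54 (edgeR adjusted p = 6.12e-09), and all 12 libraries lay below the lowest of the other group. Cytokines and chemokines had 21 of 31 members higher (22 adjusted over the list alone, median 1.14, camera adjusted p = 5.67e-08), among them IL6 at 3.24 ± 0.53. The TLR and NF-kB list had 24 of 38 higher (26 higher and 1 lower adjusted over the list alone, median 0.73, camera adjusted p = 9.45e-07). Both had an adjusted p = 0.137 with an estimated correlation. The NF-kB subunit genes NFKB2 and RELB were higher by 1.54 ± 0.25 and 1.41 ± 0.25, the adhesion molecule gene ICAM1 by 1.65 ± 0.28 and the soluble pattern receptor gene PTX3 by 2.42 ± 0.42. The interferon gamma list had 11 of 24 higher (15 adjusted over the list alone, median 0.71, camera adjusted p = 9.95e-05, adjusted p = 0.474 with an estimated correlation), with IRF1 at 1.42 ± 0.31 and WARS1 at 1.63 ± 0.25. The type I interferon list had 7 of 36 higher (4 adjusted over the list alone, median 0.64) and was not called (camera adjusted p = 0.0965), but 7 of the 37 fits that left out 1 library called it, namely LOW_SE replicate 5 (adjusted p = 0.0129) and HIGH_SE replicates 2, 3, 4, 6, 8 and 12 (0.0186 to 0.0498). Without the 5 libraries of high mitochondrial mRNA share it was called too (median 1.03, adjusted p = 0.000376), as it was with the share of reads outside genes in the model (0.0232). Hypoxia genes were higher in 11 of 25 and lower in 1 (11 and 1 adjusted over the list alone, median 0.6, camera adjusted p = 0.00098), and the IL-6 and STAT3 list in 10 of 19 and lower in 2 (10 and 2 adjusted over the list alone, median 0.55, camera adjusted p = 0.021); both had an adjusted p = 0.595 with an estimated correlation, and the call of the latter ended without LOW_SE replicate 7 (0.0553). Cell death and p53 targets were higher in 10 of 22 and lower in 2 (12 and 2 adjusted over the list alone, median 0.39, camera adjusted p = 0.0031, adjusted p = 0.22 with an estimated correlation), with BBC3 at 2.43 ± 0.27 and the death receptor gene FAS at 2.14 ± 0.41. HAMP was higher by 1.67 ± 0.47, and ANGPTL8, an insulin-responsive lipase regulator gene, by 3.29 ± 0.39. The acute phase list was not among the lists called, with a mean log2 CPM of 8.96 ± 0.38 in HIGH_SE and 9.22 ± 0.2 in LOW_SE. LBP lay below the LOW_SE mean in all 12 HIGH_SE libraries, and FGB and FGG in 11 of 12. HAMP, LCN2 and PIGR lay above it in 9, 9 and 10 of 12.

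Lower lists were urea cycle and amino acid catabolism with 20 of 31 (22 adjusted over the list alone, median -0.96, camera adjusted p = 5.79e-10), fatty acid oxidation with 23 of 33 and 1 higher (23 and 1 adjusted over the list alone, median -0.86, camera adjusted p = 7e-09), the TCA cycle list with 21 of 30 (24 adjusted over the list alone, median -0.54, camera adjusted p = 7e-09) and xenobiotic metabolism with 11 of 17 (12 adjusted over the list alone, median -1.37, camera adjusted p = 2.6e-06). Each of these had an adjusted p = 0.111 with an estimated correlation. OTC differed by -3.37 ± 0.47, the methyl transfer genes GNMT and BHMT by -3.17 ± 0.43 and -4.04 ± 0.52, ACADM by -1.59 ± 0.22, the succinate dehydrogenase gene SDHA by -0.56 ± 0.11 and SULT2A1 by -2.32 ± 0.39. Gluconeogenesis had 8 of 20 lower (9 adjusted over the list alone, median -0.69, camera adjusted p = 0.000294) and bile acid synthesis and transport 10 of 20 (13 adjusted over the list alone, median -0.91, camera adjusted p = 1.31e-05); both had an adjusted p = 0.137 with an estimated correlation. FBP1 differed by -2.25 ± 0.34, the bile acid and drug exporter gene ABCC2 by -2.25 ± 0.37, and the liver pyruvate kinase gene PKLR by -2.54 ± 0.4. PCK1 differed by -0.61 ± 0.32 and did not pass (adjusted p = 0.137), but passed at -1.02 without HIGH_SE replicate 6. Oxidative phosphorylation had 27 of 53 lower (28 adjusted over the list alone, median -0.37, camera adjusted p = 5.73e-06), and Kupffer cell markers 6 of 19 (6 adjusted over the list alone, median -0.48, camera adjusted p = 0.0308); both had an adjusted p = 0.595 with an estimated correlation. The Kupffer call ended without LOW_SE replicate 7, LOW_SE replicate 8 or HIGH_SE replicate 10 (adjusted p from 0.0528 to 0.0957) and with the share of reads outside genes in the model (0.179). Complement had 9 of 24 lower and 1 higher (9 and 1 adjusted over the list alone, median -0.46, camera adjusted p = 0.00387, adjusted p = 0.405 with an estimated correlation). The hepatocyte secreted list had 7 of 23 lower and 1 higher (7 and 1 adjusted over the list alone, median -0.14, camera adjusted p = 0.0342, adjusted p = 0.701 with an estimated correlation), with ALB at -2.2 ± 0.41. It was not called without HIGH_SE replicates 1, 3, 7 or 12 or LOW_SE replicates 5, 7 or 12, each left out alone (adjusted p from 0.0542 to 0.112), and its median was 0.01 without LOW_SE replicate 7. Nor was it called without the 5 libraries of high mitochondrial mRNA share (0.0737), with the share of reads outside genes in the model (0.0933) or with fry (0.0567). Glycolysis was not called (5 of 27 higher and 10 lower, 5 and 10 adjusted over the list alone, camera adjusted p = 0.273), nor were glycogen metabolism (camera adjusted p = 0.187) or the pentose phosphate pathway (0.25). Fry did call glycogen metabolism (median -0.19, fry adjusted p = 0.000884).

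HIGH_SE replicate 2 held 1750 CPM of HSPA6 and 5230 CPM of HSP70.2, inducible heat shock genes, where the other HIGH_SE libraries held 0.89 to 56.7 and 24.7 to 760 CPM. Both have close paralogues, so reads shared between copies leave their counts uncertain. Without that library HSPA6 went from 6.28 to 2.94, HSP70.2 from 4.12 to 2.38, and the prostaglandin synthase gene PTGS2 from 3.03 to 1.88, all 3 still passing. The edgeR test called 4965 genes, 2630 higher and 2335 lower, and camera 16 lists, none with an estimated correlation (smallest adjusted p 0.111; fry called 19). With the share of reads outside genes as a covariate, which averaged 4.81 ± 0.76% in HIGH_SE and 3.76 ± 0.82% in LOW_SE, 2960 genes were called.

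The interaction compares the infection response between both glucose supplies, as the log2 fold change under high minus that under standard glucose. Many transcripts of glucose production and amino acid breakdown had a positive interaction. A higher response here means a higher signed fold change, not necessarily a larger one. Mean log2 CPM of the urea cycle list went from 5.35 in HIGH_CON to 6.24 in HIGH_SE, and from 8.04 in LOW_CON to 7.37 in LOW_SE. PCK1 had an interaction of 4.68 ± 0.6 (edgeR adjusted p = 1.62e-05), CPS1 of 3.42 ± 0.46 and AASS of 3.41 ± 0.44. CPS1 rose by 2.64 ± 0.37 with infection under high glucose and fell by 0.78 ± 0.3 on the log2 scale under standard glucose, the latter narrowly past the threshold (edgeR adjusted p = 0.0496). FBP1 rose by 1.16 ± 0.43 (adjusted p = 0.0354) and fell by 2.79 ± 0.38, an interaction of 3.96 ± 0.6. The urea cycle and amino acid catabolism list had 17 of 31 members with a higher response under high glucose (24 adjusted over the list alone, median 1.44, camera adjusted p = 2.28e-21, and 0.00573 with an estimated correlation), among them NAGS, which makes the activator of CPS1, and the ornithine carrier gene SLC25A15. Gluconeogenesis had 10 of 20 (14 adjusted over the list alone, median 1.2, camera adjusted p = 6.83e-16, and 0.000773 with an estimated correlation), and the insulin and FOXO list 4 of 20 (9 higher and 2 lower adjusted over the list alone, median 0.84, camera adjusted p = 2.03e-05, and 0.00623 with an estimated correlation). Coagulation had 5 of 29 (13 adjusted over the list alone, median 0.96, camera adjusted p = 8.18e-10, and 0.0264 with an estimated correlation), with F7 at 1.97 ± 0.37. Complement had 5 of 24 (11 adjusted over the list alone, median 0.85, camera adjusted p = 7.23e-08, and 0.0323 with an estimated correlation), with C3 at 1.6 ± 0.35 and the complement inhibitor gene SERPING1 at 1.64 ± 0.27. Iron handling had 2 of 21 (3 adjusted over the list alone, median 0.56, camera adjusted p = 0.00257, and 0.0323 with an estimated correlation).

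Camera called 19 more lists upward, with adjusted p from 0.133 to 0.603 with an estimated correlation. With the share of reads outside genes in the model 16 of the 25 lists stayed called. The 9 that did not were glycolysis, fatty acid oxidation, oxidative phosphorylation, mitochondrially encoded genes, bile acid, xenobiotic metabolism, oxidative stress, Kupffer cell markers and B cell markers (adjusted p from 0.0579 to 0.262). Fry called 16, of which 15 were among the 25. It did not call the IL-6 and STAT3, hypoxia and stellate cell lists, nor the first 6 and the Kupffer cell markers of those 9 (0.0532 to 0.35). With HIGH_CON replicates 5 and 6 summed, mitochondrially encoded genes, oxidative stress and Kupffer cell markers lost their calls (0.0537 to 0.0566). The first of these also did with the ambiguous share in the model (0.159), and oxidative stress with the stricter filter (0.0521). Cytokines and chemokines had 3 of 31 members higher (8 adjusted over the list alone, median 1.02, camera adjusted p = 4.11e-06, adjusted p = 0.156 with an estimated correlation), with CCL4 at 2.47 ± 0.54. The IL-6 and STAT3 list had 4 of 19 (7 adjusted over the list alone, median 0.39, camera adjusted p = 0.00173, adjusted p = 0.296 with an estimated correlation), with SOCS1 at 3.42 ± 0.67. B cell markers (median 0.67, camera adjusted p = 0.00981, adjusted p = 0.195 with an estimated correlation) were called with no member passing over all genes or adjusted over the list alone. Cholangiocyte markers (median 0.34, camera adjusted p = 0.00669, adjusted p = 0.194 with an estimated correlation) had 1 of 14 higher (2 adjusted over the list alone), and oxidative stress genes (median 0.32, camera adjusted p = 0.0233, adjusted p = 0.194 with an estimated correlation) 2 of 21 (4 higher and 1 lower adjusted over the list alone). The call of the latter ended without LOW_CON replicate 5, HIGH_CON replicate 5 or HIGH_CON replicate 6 (adjusted p from 0.0523 to 0.0604). Mitochondrially encoded genes (median 0.66, camera adjusted p = 0.0396, adjusted p = 0.603 with an estimated correlation), with no member passing over all genes or adjusted over the list alone, lost their call in 17 of the 37 fits that left out 1 library. These were HIGH_SE replicates 3, 5, 6 and 8, LOW_SE replicates 1, 3, 6, 8, 11, 12 and 13, HIGH_CON replicates 1, 2, 4, 5 and 6 and LOW_CON replicate 5 (adjusted p from 0.0502 to 0.17, median 0.19 without HIGH_SE replicate 8). The calls of 3 others among the 19 ended in such fits. Kupffer cell markers lost theirs without HIGH_SE replicate 3 or HIGH_CON replicates 2, 5 or 6, each left out alone (0.0571 to 0.0793). Bile acid synthesis and transport did so without HIGH_SE replicate 3, HIGH_CON replicate 4 or LOW_CON replicate 4 (0.0514 to 0.0777). Oxidative phosphorylation did so without LOW_CON replicate 5 (0.0794). Glycogen metabolism was not called (camera adjusted p = 0.0521) but was called in 14 such fits. These were HIGH_SE replicates 1, 4, 7, 8, 9 and 11, LOW_SE replicates 4, 9, 10 and 11, HIGH_CON replicate 1 and LOW_CON replicates 1, 5 and 6 (0.0321 to 0.0479). Glycogen metabolism was called too with fry (0.0143), with the ambiguous share in the model (0.0409) and with the erythroid score (0.0497). The type I interferon list was not called (median -0.01, camera adjusted p = 0.546), nor the interferon gamma list (median 0.1, camera adjusted p = 0.945). SPOCK1, a secreted proteoglycan gene, went the other way: it fell by 1.14 ± 0.41 (edgeR adjusted p = 0.0308) on the log2 scale with infection under high glucose and rose by 3.32 ± 0.48 under standard glucose, an interaction of -4.47 ± 0.62. The edgeR test called 570 genes, 352 with a higher and 218 with a lower response under high glucose. That count was 367 without HIGH_CON replicate 5, 381 with replicates 5 and 6 of HIGH_CON summed and 368 without a filter. It was 880 with 2 surrogate variables, 941 with DESeq2 and 2429 with voom and sample quality weights (1283 higher and 1146 lower).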

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

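The tests of the share of hepatocytes, of both read assignment trends, of the summed replicates, of a library deposited again and of splits of the residuals were chosen only after the results were seen.

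The infection response differed between glucose supplies, by edgeR's interaction test, for enzymes of amino acid breakdown and glucose production. The interaction was 3.41 for AASS (adjusted p = 1.62e-05), 3.42 for CPS1 (2.31e-05), 2.23 for NAGS (0.000709), 1.91 for SLC25A15 (0.000709), 4.68 for PCK1 (1.62e-05), 3.96 for FBP1 (0.000126), 4.39 for G6PC1 (0.000125), 4.53 for SDS (0.00431) and 4.23 for GYS2 (0.000145). Without HIGH_CON replicate 3 it was 5.2 for G6PC1 and 5.46 for SDS, and SDS was at 3.38 without LOW_CON replicate 5. Conjugation and secreted protein genes differed too, with 4.01 for SULT2A1 (0.000709, and 4.91 without HIGH_CON replicate 3), 3.23 for ALB (0.00656), 1.97 for F7 (0.0016), 1.51 for F9 (0.00704), 1.6 for C3 (0.00593) and 1.64 for SERPING1 (0.000482). Among signalling and stress genes it was 2.47 for CCL4 (0.00704), 3.42 for SOCS1 (0.00236), 4.55 for HSP70.2 (0.0165), -3 for GDF15 (0.0148) and -4.47 for SPOCK1 (3.59e-05). HSP70.2 was at 2.82 without HIGH_SE replicate 2, and GDF15 at -2.21 and no longer passing without HIGH_CON replicate 4 (adjusted p = 0.0693). Lists that differed with an estimated correlation were urea cycle and amino acid catabolism (median 1.44, camera adjusted p = 0.00573), gluconeogenesis (1.2, 0.000773), insulin and FOXO (0.84, 0.00623), coagulation (0.96, 0.0264), complement (0.85, 0.0323) and iron handling (0.56, 0.0323).

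The first pattern weighed is the low level of amino acid catabolism and gluconeogenesis transcripts in uninfected livers under high glucose. Read assignment trends are argued against as the whole cause, since the median of the urea cycle list was -2.41 (jackknife SE 0.24) with the ambiguous share in the model and -1.97 (SE 0.24) with the share of reads outside genes, against -2.44 without either. The median of the urea cycle list minus that of the hepatocyte secreted list was -1.31 (SE 0.32). That argues against a smaller share of hepatocytes as the whole cause only under 2 assumptions. These are that it lowers all their transcripts alike and that the secreted list stems from hepatocytes alone. A smaller contribution of the hepatocyte share stays open: the 153 markers of 9 other cell types, which a lower share would raise, had a median of -0.25 (SE 0.17) with 1 higher and 14 lower, and 52.2% of the hepatocyte secreted list lay within 2 standard errors of its median. The glucose supply itself, the biological difference in the design, stays open with it.

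The second pattern is the different infection response of these transcripts. An animal counted again in HIGH_CON is argued against as the cause of both list calls, since with replicates 5 and 6 summed both passed with an estimated correlation (larger adjusted p = 0.00637), although called members went from 10 to 8 of 20 and from 17 to 13 of 31, lists from 25 to 22 and genes from 570 to 381. A trend followed by the share of reads outside genes is argued against as the whole cause, since with that share in the model the median was 1.12 (SE 0.27, camera adjusted p = 4.23e-12) for gluconeogenesis and 1.35 (SE 0.23, 2.96e-16) for urea cycle and amino acid catabolism. A stricter limit, applied to the same gluconeogenesis median, could not decide on that trend. Both limits were chosen after the results were seen. A contribution of that trend stays open, and so does glucose supply as the biological explanation. The response under high glucose starts from the low uninfected level of the first pattern, so both patterns share the HIGH_CON libraries.

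The third pattern is the closeness of replicates 5 and 6 of HIGH_CON. A library deposited again is argued against, since the variance of their difference was 7.58 times its sampling variance over 13512 genes. Preparation of 1 animal or tissue sample again may explain it: 2 genes had at least 20 reads in 1 of the pair and none in the other, against 3 to 71 in the other 173 pairs, a narrow margin, and 42 genes differed over 4-fold against at least 76 elsewhere. The labels list them as separate samples, and no biological explanation was tested.

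Within the uninfected groups of 6, single libraries lay apart in 13 of 210 quantities tested, where chance alone gives about 10.5. In LOW_CON replicate 5 the mean log2 CPM was 10.92 for the hepatocyte secreted list (others 10.07 to 10.29) and 11.98 for mitochondrially encoded genes (10.77 to 11.07), and log2 CPM was 9.65 for C8B (8.89 to 9.17) and 1.96 for TAP1 (2.71 to 3.14). HIGH_CON replicate 3 was at 12.01 for mitochondrially encoded genes (10.19 to 10.62), 14.59% for mitochondrial mRNA (6.33 to 7.87) and 7.95 for IGFBP1 (9.77 to 10.26). HIGH_CON replicate 4 was at 4.63 for cell death and p53 targets (3.79 to 4.03), 3.77 for F7 (5.13 to 5.83) and 1.7 for HSPA6 (-1.94 to -0.65), and its 20 most abundant genes took 13.62% of reads (18.38 to 20.91). CXCL8 was at 1.28 in LOW_CON replicate 4 (-1.14 to -0.28), and 6.6% of reads lay outside genes in LOW_CON replicate 6 (3.55 to 4.67).

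Reads that were given to no gene differed between groups by exact permutation tests, adjusted over 12 comparisons. These tests counted HIGH_CON replicates 5 and 6 as separate samples. Reads with several alignments made up 7.98 ± 0.9% in HIGH_SE and 6.2 ± 0.43% in HIGH_CON (adjusted p = 0.00259), and 7.77 ± 0.54% in LOW_SE and 6.39 ± 0.34% in LOW_CON (0.000884). Reads outside genes made up 6.51 ± 1.1% in HIGH_CON and 4.42 ± 1.14% in LOW_CON (0.039). Infected livers had 4.81 ± 0.76% in HIGH_SE, lower than HIGH_CON (0.00432), and 3.76 ± 0.82% in LOW_SE, which did not pass against LOW_CON (0.348).

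Whether other divisions of the samples call as many genes was tested with 100 splits per contrast, each fitted on the compared groups alone and counting the real split. For infection under high glucose 1 split, the real one, called as many as the real 4048 genes, and the highest other called 1372. For infection under standard glucose it was 1 split at 4015 genes against 60, for glucose in infected livers 1 at 4351 against 79, and for glucose in uninfected livers 1 at 4009 against 1436, from a split that kept 10 of 12 libraries as in the real one. For the interaction 2 splits reached the real 570 genes, and the other called 1251. That split kept all 12 uninfected libraries and 15 of 25 infected libraries in their real groups, so the real difference between the uninfected groups enters its count. Splits of that kind test for no glucose effect at all, so 100 others divided the residuals of log2 CPM after the additive effects of infection and glucose were taken out. There limma called 581 genes in the real split, which 1 split, the real one, reached, and the highest other called 6. For the 4 group counts, and by the residuals for the interaction, no other split tried reached the real count. These shares, 1 of 100 each, argue against a chance division of independent samples, but do not exclude chance. The splits took every library as independent, including the pair of HIGH_CON libraries with close counts, and were not repeated with that pair merged. Litter and batch are not in the labels, so the splits could not allow for them either.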

How the results depend on the processing

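The summed replicates, the sex term, both read share covariates and the fit without 5 libraries of high mitochondrial mRNA share were chosen only after the data were seen. No call turned to the opposite direction. The median of the hepatocyte secreted list between glucose supplies in infected livers, -0.14, was 0.01 without LOW_SE replicate 7, where it was not called (adjusted p = 0.102). RLE factors, the stricter filter, removal of the 20 most abundant genes, the erythroid score, the sex term, the ambiguous share, fits of the compared groups alone, the summed replicates and the fit without 5 libraries each left the counts computed under them within 1.5 times those reported. Fits of the compared groups alone gave no list or interaction counts, and removal of the 20 most abundant genes no list counts.

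Limma voom with sample quality weights called 7209 genes for infection under high glucose, 6619 for glucose in uninfected livers and 2429 for the interaction, and gave a correlation of infection fold changes of 0.657. For the interaction, DESeq2 called 941 genes, 2 surrogate variables 880 and no filter 368. With DESeq2 the median interaction was 0.163 over all genes with any read, a wider set than the 14025 genes of the edgeR test. That median therefore cannot show whether its fold changes are shifted against those of edgeR. With the share of reads outside genes in the model, 2960 genes were called for glucose in infected livers (2845 shared with the 4965 reported) and 1879 for glucose in uninfected livers (1711 shared with 3852), and 16 lists for the interaction. For infection it called 3346 genes under high glucose (2857 shared with 4513) and 3793 under standard glucose (3523 shared with 4098). The cause was not tested, except that this share differed between the uninfected groups and between HIGH_SE and HIGH_CON (exact permutation test, adjusted p = 0.00432). It was not tested between HIGH_SE and LOW_SE. Its correlation with principal component 2 of log2 CPM, which held 20.4% of the variance, was r = 0.81. All HIGH_CON libraries lay above all LOW_CON libraries on that component. The ambiguous share correlated at r = -0.88 with component 3, which held 9.8%.

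Camera with an estimated correlation called 8 lists for infection under high glucose, 0 under standard glucose, 0 for glucose in infected livers, 10 in uninfected livers and 6 for the interaction. At 0 lists, camera with the preset correlation had called 21 and 16, and fry 24 and 19. Fry called 16 lists for the interaction.

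Leaving out 1 library gave 3885 to 4744 genes for infection under high glucose, 2977 to 4584 under standard glucose, 4464 to 5643 for glucose in infected livers, 3330 to 4031 in uninfected livers, and 367 (without HIGH_CON replicate 5) to 718 (without LOW_SE replicate 7) for the interaction. Lists called ran from 19 to 21, 18 to 23, 14 to 18, 19 to 20 and 22 to 27 in that order, and the correlation from 0.699 to 0.734. Over all lists and fits that left out 1 library, 55 list results fell below the threshold, 43 passed it and 7117 kept their side.

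With replicates 5 and 6 of HIGH_CON summed, the interaction called 381 genes, 379 of them among the 570. Of the gene results in the text, PCK1 between glucose supplies in infected livers (-0.61, adjusted p = 0.137) passed with voom (-0.93), without the 5 libraries (-0.96) and without HIGH_SE replicate 6 (-1.02). The interaction of GDF15 ended without HIGH_CON replicate 4 (-2.21, adjusted p = 0.0693). The other gene results of the report that were refitted, 144 in all with these, kept their call. Those that passed also kept their direction. For those that did not pass, such as ALB with infection under high glucose, the direction was not compared. The genes in the text were picked after their values were seen, and some that depended on 1 library or setting were left out. Their steadiness therefore follows in part from that choice and says little about other genes. Infection fold changes given only beside an interaction, and those of DIRAS3, PDIA4, CHAC1 and ASNS, were not refitted. Depth limited genes of low count, which the filter removed. No paired analysis was possible because the labels give no replicate, litter or batch numbers that pair the samples.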

Other observations

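The tests of ATF4 targets and chaperones, the erythroid relation and the choice of single genes were made only after fold changes had been seen. The test of imprinted genes was written before its result.

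Transcripts of endoplasmic reticulum chaperones rose with infection at both glucose supplies and were lower under high glucose. Of 16 measured, 15 rose with infection under high glucose (median log2 fold change 1.13, camera adjusted p = 7.1e-08, and 0.216 with an estimated correlation) and 14 under standard glucose (1.07, 1.33e-09 and 0.176). Between glucose supplies 10 were lower in infected livers under high glucose (-0.81, 7.46e-07 and 0.246). PDIA4, a disulfide isomerase gene, changed by 1.54 ± 0.32 and 1.66 ± 0.32 with infection, and by -1.47 ± 0.24 between glucose supplies in infected livers.

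Among infected livers, erythroid and cell cycle transcripts rose and fell together. The mean log2 CPM of both lists, which share 0 members, correlated over the 12 HIGH_SE libraries with r = 0.96 (permutation p = 6e-05, adjusted p = 0.00012) and rho = 0.85 (0.00088, adjusted 0.00176). Without the 2 libraries farthest from the median, r was 0.9. Over the 13 LOW_SE libraries r was 0.81 (permutation p = 0.00103) and rho 0.64 (0.0207), with r = 0.83 without the 2 farthest. The adjusted p of this relation covers the 2 infected groups alone, not the other pairs of lists that could have been chosen. The uninfected groups were not tested for this relation, so it is not shown to be particular to infected livers.

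Heat shock transcripts stood out in 1 infected liver. HIGH_SE replicate 2 had a log2 CPM of 9.47 for HSPH1, 10.79 for DNAJB1 and 8.12 for BAG3, in addition to its HSPA6 and HSP70.2.

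High glucose in uninfected livers raised GDF15, STC2 and ATF3, and the ATF4 arm of the stress response without its chaperone arm may account for that. The 23 measured ATF4 targets other than these 3 genes were higher as a list (11 higher, 1 lower, median 0.65, camera adjusted p = 0.0275), but not with an estimated correlation (adjusted p = 0.407). Chaperones were lower in 7 of 16 (median -0.72, camera adjusted p = 0.000351, and 0.392 with an estimated correlation). CHAC1, an ATF4 target, differed by 3.42 ± 0.73, whereas the asparagine synthetase gene ASNS differed by -0.56 ± 0.25 (edgeR adjusted p = 0.0907). The same list was higher in infected livers under high glucose, with 14 of 23 members (median 0.9, camera adjusted p = 1.11e-07, and 0.176 with an estimated correlation).

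The imprinted genes PEG10 and DIRAS3 fell with infection, by 4.51 ± 0.61 and 3.5 ± 0.4 on the log2 scale under high glucose and by 3.3 ± 0.58 and 2.5 ± 0.39 under standard glucose. PEG10 was at -3.35 under high glucose without HIGH_CON replicate 1. A fall of imprinted genes as a group was not borne out: the 15 others had medians of -0.15 and -0.54, and the larger of both camera adjusted p was 0.303.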
